A study of Drosophila melanogaster with 12 samples.

How the data were processed

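Total RNA from Drosophila melanogaster embryos of the C-S strain was measured on 12 arrays with 1 colour each, 3 in each of 4 groups. The groups, taken from the sample titles and sources, were control and X-ray treated embryos at stages 9 to 11 (the sensitive window in the titles) and control and X-ray treated embryos at stages 13 to 15 (the resistant window). Treated embryos were collected 15 to 20 minutes after treatment, per the labels. The X-ray dose is not given in the sources used here. The replicate number came from each title. No label says that same-group samples came from separate collections of embryos, so the p-values measure the spread between these samples, part of which may be technical.

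The deposited table holds 14010 probe sets, of which 44 are array controls and 13966 are gene probe sets. Its values are deposited intensities on a linear scale. The scanner software and the normalization that the authors used are not given in the sources used here. In the deposited values, each array's mean after trimming 2% at each end is the same to within 0.00230%, so the arrays had been scaled to a common mean before deposit. A limit of 5% on that spread had been set for treating the table as already scaled, and no further normalization was applied. Such a scaling removes any change of total signal shared by all probe sets. Whether background had been subtracted is not given either, so fold changes of weak probe sets are uncertain in both directions.

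Gene names were taken from the synonyms of a RefSeq gene table (assembly Release 6 plus ISO1 MT), matched to the probe-set identifiers without regard to case. This named 133 probe sets (131 genes), none with several genes. The other 13833 gene probe sets are not named here, and the files do not pair them with names. They enter every count, and 4 of them are given by identifier. Of these, 153035_AT and 143796_AT passed the test for X-rays, while 143680_AT (the next rise by p) and 150671_F_AT (the lowest log2 difference after X-rays at stages 9 to 11) were chosen after their values were seen. No coordinates were used.

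Intensities were transformed as log2(value + 13.3), with the pseudocount at the 25th percentile of the table. Fold changes and log2 differences are therefore on the log2(value + pseudocount) scale and understate the change of weak probe sets. Control probe sets were left out. Probe sets above 29.9 (the 40th percentile of the table) on at least 3 of the 12 arrays, whatever their group, were kept, which left 10139 probe sets and 107 named genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean level), with 4 group means, 8 residual and 7.26 prior degrees of freedom, 2-sided tests and Benjamini-Hochberg adjustment within each comparison at 0.05. The comparisons were X-ray against control in each window, the difference between those effects, and the later against the earlier window in control embryos. The number of arrays limits the precision: the median half-width of the 95% confidence interval was 0.725 on the log2 scale, and 1.03 for the difference between the X-ray effects.

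Before the data were examined, the tests, the other settings to be tried, 21 gene lists and the rule for named genes were fixed. The rule takes, for each X-ray effect and for the stage difference, up to 10 named genes that rose and 10 that fell with an adjusted p under 0.05 and no overlap between the groups' values. Where fewer than 5 pass in a direction, it fills up to 5 by the smallest unadjusted p, given as values only. For the difference between the X-ray effects it takes 5 in each direction. A list needed 3 tested genes for a set test (camera in limma, with a preset correlation of 0.01 and with an estimated one). Only the immune list reached this, with 3 of its 22 genes tested. The heat shock, Polycomb and heterochromatin, ribosomal protein and early segmentation lists had 1 tested gene each. The other 16 lists, among them the inhibitor-of-apoptosis antagonists, apoptosis machinery, DNA damage checkpoint, DNA repair and cell type markers, were not analysed by name here.

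The code was tested on simulated data over 10139 probe sets, with the real mean of each window and the fitted spreads. In each simulated fit, 50 probe sets were changed at each of the fold sizes together. For X-rays in the sensitive window it recovered 6% of changes of 1.5-fold, 30% of 2-fold, 98% of 4-fold and 100% of 8-fold, with 4 false calls. For the resistant window it recovered 4%, 28%, 88% and 100%, with 5 false calls. These shares overstate the power where few probe sets change, since many changed ones loosen the Benjamini-Hochberg cut. The simulated noise was also independent, with no effect of the replicate number. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so single probe sets were tested only through the model. Alternatives were other normalizations, pseudocounts and filters, no trend in the moderation, array weights, the replicate number as a block, only the groups compared, each array left out in turn and, added after the data were seen, all 4 arrays numbered 3 left out.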

Results

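The series compares the early transcript response to X-rays between embryos in a window the sample titles call sensitive (stages 9 to 11) and embryos in a window they call resistant (stages 13 to 15). Total RNA was measured on 12 arrays, 3 per group, as scaled intensities. Arrays of the same window ranked the tested probe sets alike, with Spearman correlations across probe sets of 0.816 to 0.945, against 0.617 to 0.752 between windows. The largest share of identical values between any pair of arrays was 0.528%, so all 12 arrays were treated as separate samples.

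The array controls differed by replicate number, in all 4 groups alike. The BioB spike-in transcript (middle probe set) read 1376 to 1533 on arrays numbered 1, 425 to 738 on those numbered 2 and 226 to 299 on those numbered 3. The brightest probe set read 20207 to 24796, 22375 to 24755 and 11073 to 12532 in the same order. The 5′ over 3′ ratio of the translation factor transcript eIF-4a, a sign of RNA integrity and labelling length, was 0.0378 to 0.0550, 0.0524 to 0.0798 and 0.140 to 0.200. Each number holds 1 array of every group, so values within a number are given beside the X-ray results.

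The first comparison asks which transcripts changed 15 to 20 minutes after X-rays in embryos at stages 9 to 11. Of 10139 tested probe sets, 2 passed the adjusted threshold in limma, 1 higher and 1 lower. 153035_AT rose 3.94-fold, from an intensity of 155 ± 17.8 in controls to 651 ± 68.4 in irradiated embryos (SD, n = 3 each). Its log2 difference was 1.98 ± 0.27 (SE, adjusted p = 0.0108), and within numbers 1, 2 and 3 it was 2.04, 1.91 and 1.99. 143796_AT fell 5.49-fold, from 183 ± 86.1 to 20.0 ± 5.68 (SD, n = 3 each). Its log2 difference was −2.46 ± 0.33 (SE, adjusted p = 0.0108), with −2.72, −2.79 and −1.86 within the numbers. The irradiated values of 143796_AT lay below the filter value of 29.9, so its fold depends on signal close to background.

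Another pair of probe sets did not pass the threshold but had differences of 1 sign within all 3 numbers. 143680_AT read 101 ± 22.1 in controls and 381 ± 98.1 in irradiated embryos, a log2 difference of 1.78 ± 0.29 (SE, adjusted p = 0.0662), with 1.61, 1.89 and 1.83 within numbers. Among 23 alternatives it passed only with the replicate number as a block (adjusted p = 0.0354), with array weights (0.0383), with 4 times the pseudocount (0.0165) and without resistant X-ray replicate 1 (0.0430). In the others the adjusted p reached 0.575, without sensitive control replicate 1, and it was 0.197 without the trend in the moderation. 150671_F_AT read 1418 ± 850 and 253 ± 202, a log2 difference of −2.82 ± 0.68 (SE, adjusted p = 0.885), with −2.70, −1.85 and −3.90 within numbers. Its irradiated array numbered 3 read 23.4, below the filter value, so the last of these rests on signal close to background. Without that array the log2 difference was −1.69 (adjusted p = 0.360).

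No named gene passed in this window: of 107 tested, 6 had an unadjusted p under 0.05 and 0 an adjusted one, over all probe sets or over the named genes alone. The smallest unadjusted p of a named gene with a positive difference was that of CG6415 (log2 difference 0.96 ± 0.30, unadjusted p = 0.00572, adjusted p = 1.00). After it came ninaE (an opsin gene, 0.83), CG15203 (0.82), stc (0.36) and v, the eye colour gene vermilion (0.50). On the negative side stood CG1620 (−1.19 ± 0.42, unadjusted p = 0.0127), Jheh1 (a juvenile hormone epoxide hydrolase, −0.94), CG17896 (−0.71), CG4293 (−0.81) and en, the segment polarity gene engrailed (−0.43). The immune genes DptB, Dro and DptA, which encode antimicrobial peptides, differed by 0.05, −0.03 and −0.06. As a list they had 0 members past the threshold, also adjusted over the list alone, and camera gave p = 0.948 (p = 0.956 with an estimated correlation). DptA averaged at most 19.3 in each of the 4 groups, below the filter value of 29.9, and Dro 29.1 to 51.5, close to it, against 83.5 to 94.1 for DptB. The tests of this list, here and in the other comparisons, therefore say little about an immune response. The chaperone gene Hsp83 differed by −0.14 ± 0.21 (SE), the chromatin assembly gene Caf1-55 by −0.09 ± 0.22 and the ribosomal protein gene RpL32 by −0.06 ± 0.34.

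Over all probe sets, 312 had an unadjusted p under 0.05, against 507 expected by chance. Both calls were lost without sensitive control replicate 1 or 2, or without any of the 3 irradiated sensitive arrays (adjusted p 0.0543 to 0.134). In those 5 fits the log2 differences were 1.90 to 2.02 for 153035_AT and −2.55 to −2.23 for 143796_AT. Both were also lost without the trend in the moderation (adjusted p = 0.0948), and that of 143796_AT in a fit of the 6 sensitive arrays alone (adjusted p = 0.320). Without the 4 arrays numbered 3, a setting chosen after seeing the data, 9 probe sets passed, 1 higher and 8 lower, including both called here.

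**Figure D1:**
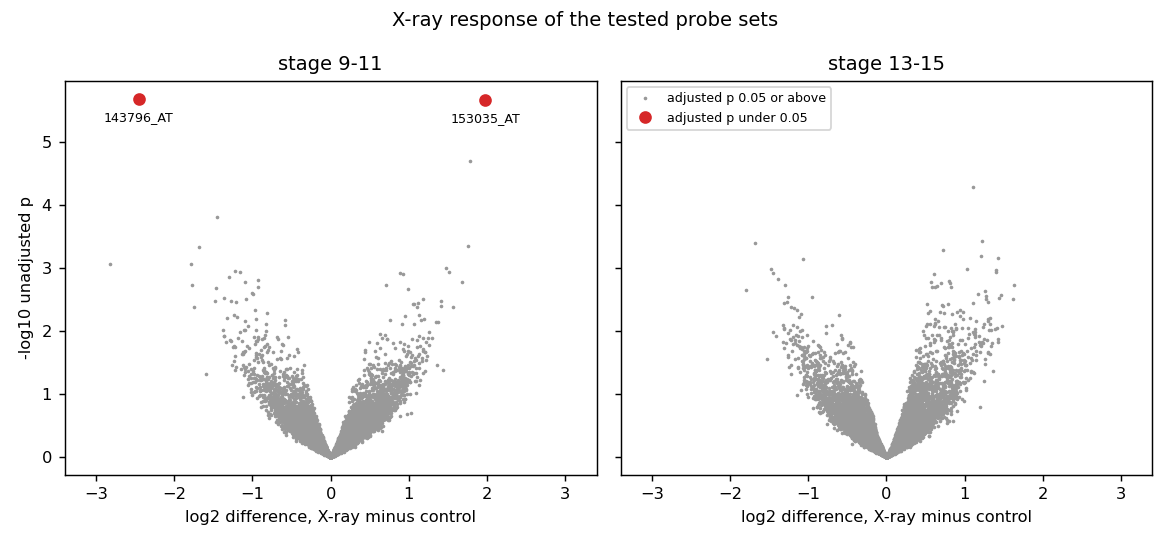
Log2 difference between X-ray treated and control embryos (horizontal axis) against −log10 of the unadjusted limma p (vertical axis), for 10139 probe sets in each window; every point is 1 probe set. The 2 red points at stages 9 to 11 are 153035_AT at 1.98 and 143796_AT at −2.46, and no red point appears at stages 13 to 15.

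The same comparison in embryos at stages 13 to 15 gave 0 of 10139 probe sets with an adjusted p under 0.05 in limma, with 503 at an unadjusted p under 0.05 against 507 expected by chance. The smallest adjusted p was 0.521. 153035_AT, higher after X-rays in the earlier window, read 94.1 ± 24.6 in controls and 44.3 ± 24.6 in irradiated embryos (SD, n = 3 each). Its log2 difference was −0.95 ± 0.27 (SE, unadjusted p = 0.00290, adjusted p = 0.925), with −1.37, −1.58 and 0.09 within numbers 1, 2 and 3. 143796_AT read 175 ± 48.5 and 279 ± 50.2, a log2 difference of 0.66 ± 0.33 (SE, adjusted p = 1.00), with 0.79, 0.45 and 0.73 within numbers. 143680_AT differed by −0.59 ± 0.29 and 150671_F_AT by 0.32 ± 0.68.

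Among the 107 named genes, 4 had an unadjusted p under 0.05 at stages 13 to 15 and 0 an adjusted one. Rtnl1, which encodes a reticulon of the endoplasmic reticulum, read 33.4 ± 34.5 in controls and 108 ± 16.6 in irradiated embryos. Its log2 difference was 1.61 ± 0.46 (SE, unadjusted p = 0.00310, adjusted p = 0.925). The next positive differences by unadjusted p were those of Caf1-55 (0.51), Prosalpha5 (a proteasome subunit, 0.42), Gprk2 (a G protein-coupled receptor kinase, 0.81) and VhaSFD (a proton pump subunit, 0.44). The negative ones were Polr1A (the large subunit of RNA polymerase I, −0.44), CG31743 (−0.83), POSH (−0.84), mRpS16 (a mitochondrial ribosomal protein, −0.35) and CG3036 (−0.31). The immune list had 0 members past the threshold, also adjusted over the list alone, and a camera p of 0.775 (p = 0.809 with an estimated correlation). Its median was 0.08, while its mean of −0.12 and the test pointed down. Hsp83 differed by 0.02 ± 0.21 (SE), RpL32 by 0.10 ± 0.34 and en by 0.38 ± 0.25. The count became 1 without resistant control replicate 3, without resistant X-ray replicate 3, and without all 4 arrays numbered 3.

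The difference between the X-ray effects of the windows was tested directly, as the sensitive effect minus the resistant effect. It passed for 2 of 10139 probe sets, the same pair as above. The effect on 153035_AT was higher in the sensitive window by 2.93 ± 0.38 on the log2 scale (SE, adjusted p = 0.0123), and the effect on 143796_AT differed by −3.11 ± 0.47 (SE, adjusted p = 0.0380). For 143680_AT the difference was 2.36 ± 0.41 (SE, adjusted p = 0.129) and for 150671_F_AT −3.13 ± 0.96 (SE, adjusted p = 0.995). Without sensitive X-ray replicate 3 that of 150671_F_AT was −2.01 (adjusted p = 0.597). The size for 143796_AT depends on the pseudocount: it was −2.17 with 4 times the pseudocount and −3.58 with 0.25 times, and the sensitive effect alone was −1.62 and −2.89. Across all tested probe sets, which are not independent replicates, the effects in the windows correlated at r = −0.0904 (Pearson) and rho = −0.0935 (Spearman). An unadjusted p under 0.05 in both windows was seen for 24 probe sets, 7 of them with the same direction. If the p-values of the windows were independent, 15.5 would be expected. Both windows share 1 estimate of the spread per probe set, which can raise the number low in both. The count of 24 therefore does not show a relation between the effects.

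Of the named genes, 4 had an unadjusted p under 0.05 for this difference and 0 an adjusted one. CG6415 (1.34), Polr1A (0.54), CG15203 (0.86), CG8219 (1.64) and Rca1 (0.52) had the smallest unadjusted p on the positive side, each with an adjusted p of 0.995. Rtnl1 (−2.08), VhaSFD (−0.77), en (−0.81), the proteasome subunit gene Prosalpha6 (−0.43) and the lipid droplet gene Lsd-2 (−0.74) had it on the negative side, also with an adjusted p of 0.995. The immune list had 0 members past the threshold, also adjusted over the list alone, and a camera p of 0.869 (p = 0.889 with an estimated correlation), with a median of −0.03 but a mean of 0.10 and a test pointing up.

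Most single arrays mattered to the calls for this difference. Neither call held when any 1 of the 4 arrays numbered 1, any 1 of the 4 numbered 2, or sensitive X-ray replicate 3 was left out. In those 9 fits the log2 difference of 153035_AT was 2.76 to 2.98, with an adjusted p of 0.0550 to 0.0653. Without resistant control replicate 3 or resistant X-ray replicate 3 only 153035_AT passed, and without sensitive control replicate 3 both passed and the count was 3. The adjusted p of 143796_AT was 0.0617 to 0.221 in the 11 fits without 1 array that ended its call, and 0.0519 to 0.0717 under quantile normalization, 4 times the pseudocount, no filter and a stricter filter, which ended it too. Neither probe set passed without the trend in the moderation (adjusted p = 0.121 for 153035_AT and 0.206 for 143796_AT), and 12 passed without the 4 arrays numbered 3, including both called here.

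**Figure D2:**
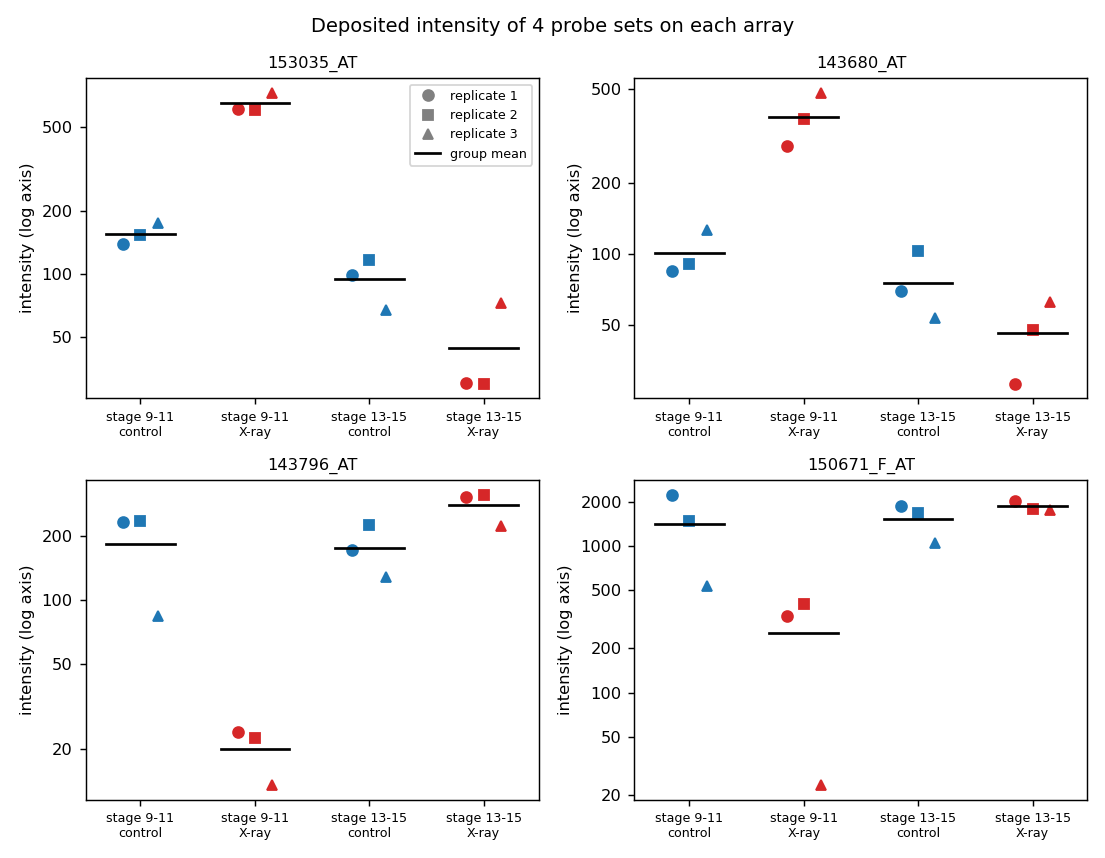
Deposited intensity (log axis, linear intensity units) of 4 probe sets on each of the 12 arrays, by group; circles, squares and triangles are replicates 1, 2 and 3, blue is control, red is X-ray treated, and the black bar is the group mean. 153035_AT averaged 155 and 651 at stages 9 to 11 and 94.1 and 44.3 at stages 13 to 15, in control and irradiated embryos, while 143796_AT averaged 183 and 20.0, then 175 and 279.

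The last comparison sets control embryos of the later window against those of the earlier one. Of 10139 probe sets, 2719 (26.8%) had an adjusted p under 0.05, 1252 higher and 1467 lower at stages 13 to 15, and 1883 of them differed by at least 2-fold (977 higher and 906 lower). Among the 107 named genes, 51 passed (23 higher, 28 lower), and 53 when adjusted over the named genes alone.

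Shmt, which encodes serine hydroxymethyltransferase of one-carbon metabolism, rose from 12.5 ± 4.63 to 177 ± 4.96 (SD, n = 3 each), a log2 difference of 2.90 ± 0.28 (SE, adjusted p = 2.79e-06). Oat, encoding ornithine aminotransferase, rose 7.09-fold from 32.2 ± 11.7 to 309 ± 72.2 (log2 difference 2.83 ± 0.30, adjusted p = 6.24e-06). The tubulin gene betaTub60D rose 6.12-fold from 91.0 ± 6.01 to 633 ± 130 (log2 difference 2.61 ± 0.17, adjusted p = 9.94e-08). Log2 differences of the other 7 were 2.50 for CG6415, 2.08 for CG9547, 1.85 for Jheh1, 1.82 for Got2 (a mitochondrial aspartate aminotransferase), 1.81 for CG31743, 1.73 for Strn-Mlck (a myosin light chain kinase gene) and 1.48 for CG17896. Their adjusted p ran from 1.91e-05 for CG6415 to 0.00899 for Strn-Mlck, whose call was lost without the arrays numbered 3 (adjusted p = 0.10). The means at stages 9 to 11 of Shmt, CG9547 (13.3), CG31743 (29.5) and Strn-Mlck (5.17) lay below the filter value of 29.9, so the sizes of their rises, and their order among the genes, depend on signal close to background. With 4 times the pseudocount the log2 difference was 1.81 for Shmt and 2.07 for Oat.

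RPA2, a subunit of the single-stranded DNA binding complex, fell 4.96-fold from 360 ± 51.7 to 61.6 ± 4.59 (SD, n = 3 each), a log2 difference of −2.31 ± 0.19 (SE, adjusted p = 8.91e-07). The early segmentation list was represented by en, which fell 3.94-fold from 310 ± 43.3 to 69.0 ± 13.3 (log2 difference −1.98 ± 0.25, adjusted p = 3.26e-05). The Polycomb and heterochromatin list was represented by Caf1-55, which fell 2.96-fold from 1249 ± 128 to 429 ± 161 (log2 difference −1.57 ± 0.22, adjusted p = 7.30e-05). The other 7 log2 differences were −1.87 for CG3036, −1.67 for CG18853, −1.67 for CG1620, −1.46 for Rtnl1, −1.34 for Sps1, −1.34 for Rca1 (a regulator of cyclin A) and −1.34 for Nmt (an N-myristoyltransferase). The mean of CG1620 at stages 13 to 15 (22.2) lay below the filter value. The call of Rtnl1 (adjusted p = 0.0279) was lost without sensitive control replicate 2 (0.0752) or 3 (0.0874) and without resistant control replicate 1 (0.125) or 2 (0.0963).

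The single genes of the other lists split. Hsp83 of the heat shock list rose 1.81-fold, from 897 ± 260 to 1615 ± 344 (SD, n = 3 each; log2 difference 0.86 ± 0.21, adjusted p = 0.00604). RpL32 of the ribosomal list did not pass (log2 difference 0.09 ± 0.34, adjusted p = 0.880). The immune list had 0 members past the threshold, also adjusted over the list alone, with a camera p of 0.814 (p = 0.842 with an estimated correlation). Its members DptB, Dro and DptA differed by 0.03, 0.38 and 0.11.

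The stage difference was measured again in the irradiated embryos, on 6 separate arrays, where 2390 probe sets passed (1217 higher, 1173 lower). Of the 2719 control calls, 2673 (98.3%) had the same direction there and 1834 (67.5%) also passed in that direction, while 1 passed in the opposite direction. Of the named genes, 39 passed in both with the same direction. RPA2 (−2.35), betaTub60D (2.77) and Shmt (2.60) differed by similar amounts in irradiated embryos. Rtnl1 (0.62 ± 0.46, adjusted p = 0.377) and CG1620 (−0.65 ± 0.42, adjusted p = 0.304) did not pass there. Within the control arrays, 2710 of the 2719 (99.7%) had the same sign between windows within all 3 numbers. They had been called on these same arrays, which nearly fixes that share, so it is no separate check.

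**Figure D3:**
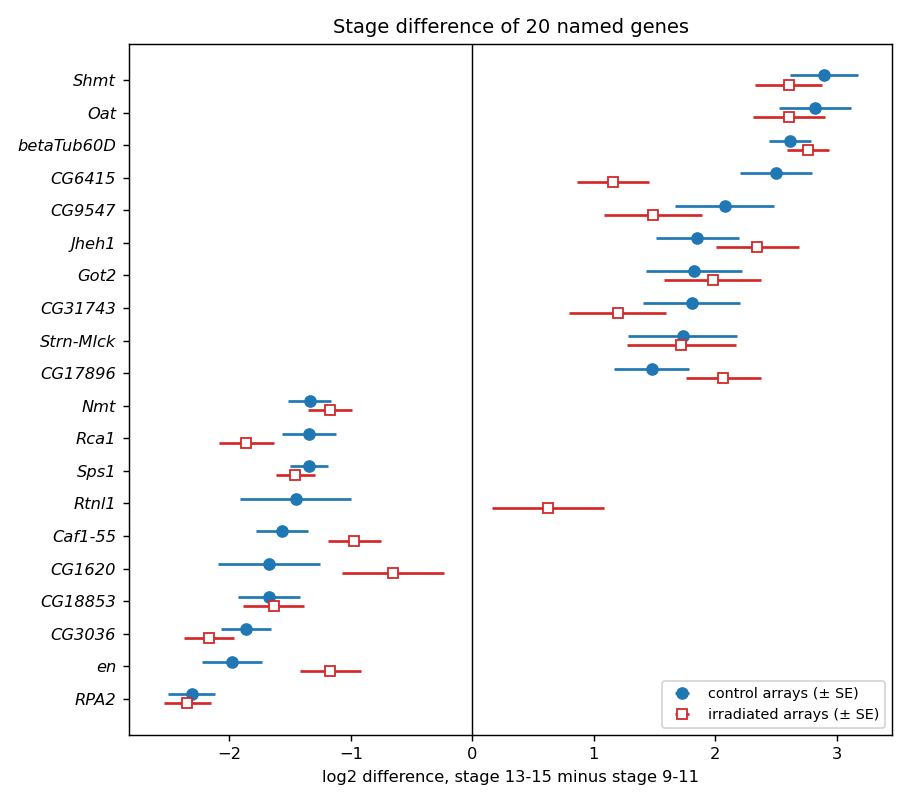
Log2 difference between stages 13 to 15 and stages 9 to 11 (horizontal axis) for the 20 named genes taken by the rule (vertical axis), with filled circles for control arrays, open squares for irradiated arrays and bars for ± 1 SE (n = 3 per group). Shmt lies at 2.90 and 2.60 and RPA2 at −2.31 and −2.35, while Rtnl1 changes sides from −1.46 in control arrays to 0.62 in irradiated arrays.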

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

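The tests of developmental age, of array batch and of the size of the difference under other scalings were chosen after the result was seen. The test of the calls under other scalings and the other splits of the arrays were planned.

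The X-ray effect differed between the windows, by the test of the difference itself, for 153035_AT (2.93 on the log2 scale, adjusted p = 0.0123) and 143796_AT (−3.11, adjusted p = 0.0380). A difference in age between irradiated and control embryos of the sensitive window is argued against by their place on an axis between the windows. For each array it ran from the mean of the sensitive arrays of the other numbers, control and irradiated, to that of the resistant ones. The largest shift in the 3 same-numbered pairs of the sensitive window was −0.0150 of its length. In the resistant window the largest was −0.0235, on number 3. For an array batch as the whole source, the arrays numbered 3 were left out of the fit. Both probe sets passed without them in limma, with differences of 3.45 and −3.37 (adjusted p = 0.00169 each). On those 4 arrays, 1 per group, the differences were 1.90 and −2.59. Both had been picked with the arrays numbered 3 included, so this agreement was partly selected for and does not exclude a batch. Of the 12 probe sets called on numbers 1 and 2, 9 had the same direction on number 3, among them 7 of the 10 not called with all arrays. A part of the number in the size, most of all for 153035_AT, stays open. The SE of such a difference was 0.66 and 0.81 from the spread of all 12 arrays, and 0.46 and 0.47 from numbers 1 and 2. Either takes the arrays numbered 3 to vary like the others, which single arrays cannot show. Quantile normalization and median centring kept at least 97.9% of both differences, so their size hardly depended on the choice among these scalings. The median log2 values of the arrays already lay at 6.44 to 6.57, so centring them could move the differences little. Neither setting reaches the scaling done before deposit, so scaling as the source of the size is not excluded. The pseudocount moved the size of 143796_AT more, to −2.17 with 4 times the pseudocount and −3.58 with 0.25 times. The call of 143796_AT did end under quantile normalization (adjusted p = 0.0585), with the difference at −3.05 ± 0.47 against −3.11 ± 0.47 before, because an adjusted p near the threshold crossed it; under median centring it was 0.0294, and over all alternatives, those without 1 array included, 0.00102 to 0.221. A response to X-rays that depends on the stage window may be a biological explanation, a hypothesis from 2 unnamed probe sets, of which 143796_AT lay close to background after X-rays.

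Of 200 possible relabellings of X-ray and control within the windows, 100 were used, the real one and 99 drawn. At least 2 calls for this difference were given by 4 of the 100, the real one included. That share lies just under the planned limit of 0.05, and the drawing of only 99 leaves it uncertain. It also holds only if arrays of different numbers can stand for each other, so chance is not excluded. The highest other relabelling gave 19. It gave the sensitive arrays numbered 3 the opposite label to the resistant arrays numbered 3. In the difference between windows all 4 then count with the same sign, so an effect shared by them would add up. Other drawn relabellings of this kind gave 0 to 2 calls. A structure of the arrays by number, which would break that condition, is therefore possible, but these counts do not settle it. With the number as a block the difference between windows had 2 calls. For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The sensitive window gave 2 calls and at most 2 in another split, with 2 of 10 splits as large. That other split placed both arrays numbered 3 on the same side, and so did the split of the resistant window with 5 calls, where the real split gave 0 and 10 of 10 splits were as large. The remaining splits with both on the same side gave 0 or 1 calls in the sensitive window and 0 in the resistant one. With the number as a block the counts were 3 and 0. The stage difference gave 2719 calls and at most 0 in another split, with 1 of 10 splits as large.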

How the results depend on the processing

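The setting without the arrays numbered 3 was chosen after seeing the data. Calls for X-rays in the sensitive window (2) became 0 without the trend in the moderation, 1 with only the groups compared and 9 without the arrays numbered 3; the other planned settings gave 2 or 3, and leaving out 1 array gave 0 to 3. The 0 calls in the resistant window stayed 0 under every planned setting except leaving out 1 array (0 to 1), and became 1 without the arrays numbered 3. Calls for the difference between windows (2) became 1 under quantile normalization, 4 times the pseudocount, no filter and the stricter filter, 0 without the trend and 12 without the arrays numbered 3, and leaving out 1 array gave 0 to 3. Some of these fits have fewer samples or another set of tested probe sets; the cause was otherwise not tested. Under the planned settings other than leaving out arrays, 153035_AT kept a log2 difference of 1.76 to 2.05 in the sensitive window and 143796_AT one of −2.89 to −1.62.

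The stage difference (2719) stayed within 1.5 times under all settings, at 2256 to 3180, and at 2138 to 2776 when 1 array was left out. The camera test of the immune list for X-rays in the sensitive window turned its direction without a filter (adjusted p = 0.674), and the cause was not tested.

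With the replicate number as a block, the calls were 3 (sensitive), 0 (resistant), 2 (difference) and 3180 (stage). The third sensitive call was 143680_AT (adjusted p = 0.0354). Deviations from group means of same-numbered arrays correlated at 0.0139 to 0.435 (0.152 to 0.435 on number 3). Between arrays of different numbers and groups the range was −0.283 to 0.139. Not every same-numbered pair was above 0.1, and the main fits do not pair the samples by number. That cut cannot show that an effect of the number is absent, and 10 of 12 arrays correlated best with an array of their own number. The p-values of the main fits leave such an effect out. Weak signals limit the folds: the share of gene probe sets above 29.9 was 56.4% to 63.2% per array.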

Other observations

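The lists of named genes in this part, and the tests on GAPDH, were chosen after the data were seen.

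A list of 6 named genes of DNA replication and the cell cycle, drawn up after their values were seen, lay lower at stages 13 to 15 in control embryos. All 6 tested had a negative log2 difference, with a median of −1.32 (−1.45 in irradiated embryos), and 4 passed the adjusted threshold. These were RPA2 (−2.31), Caf1-55 (−1.57), Rca1 (−1.34) and RfC4, a subunit of the clamp loader (−1.30), while Skp2 (−0.81) and PolZ1 (−0.84) did not pass. In a list of metabolic enzyme genes drawn up in the same way, 13 of 14 were positive, with a median of 0.57 (0.71 in irradiated embryos). Of the 14, 6 passed, among them Shmt (2.90), Oat (2.83), Got2 (1.82) and Taldo, the transaldolase of the pentose phosphate pathway (1.26). Others lay near 0, such as Gabat (0.02) and Aldh (0.10), and Pepck1 was negative (−0.66, not passed). The median of all named genes was −0.18. Under quantile normalization and median centring the medians were −1.30 and −1.39 for the replication and cell cycle list, with all 6 negative, and 0.54 and 0.50 for the metabolic list, where 1 member turned negative under median centring (12 of 14 positive).

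Genes of the transcription machinery were negative in 7 of 7 cases (median −0.75), with 5 passing, among them MED22 (−1.17), CycH (−1.17) and TfIIFalpha (−1.03). Proteasome genes were negative in 5 of 5 cases (median −0.60), with 3 passing, Prosalpha5 (−0.91), Prosalpha6 (−0.62) and Prosbeta7 (−0.60). All members of both lists were negative under both scalings too. Since the 4 lists were drawn up from genes whose values had been seen, and Caf1-55 also belongs to a list fixed before, the counts and medians describe these genes and test nothing. After X-rays no member of the 4 lists passed at stages 9 to 11, where the medians were −0.01 (replication), −0.10 (metabolic), 0.01 (transcription) and −0.08 (proteasome).

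Without the arrays numbered 3, 9 probe sets passed for X-rays in the sensitive window. Of these, 2 also passed with all arrays, and the other 7 were all falls. In the pair of sensitive arrays numbered 3, which did not enter that fit, 7 of the 9 had the same direction, 5 of the 7 added ones among them. The median log2 difference of the 8 falls among the 9 was −1.34 on numbers 1 and 2 and −1.32 on number 3, where 6 of the 8 fell. Of these 8, 143796_AT and 150671_F_AT had been picked with the arrays numbered 3 included. Both read below the filter value on the irradiated array numbered 3 (13.5 and 23.4). The agreement was therefore partly selected for, and so few probe sets cannot show that the falls repeat. The log2 difference of 150671_F_AT in that fit was −2.27 (adjusted p = 2.86e-04), and its intensity was 6.70 and 3.69 times lower after X-rays within numbers 1 and 2. Within number 3 it read 536 in the control and 23.4 after X-rays, below the filter value of 29.9. None of the 9 probe sets is named here. For the difference between windows, 9 of the 12 calls of that fit had the same direction on number 3.

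Of the control probe sets for the glycolytic gene GAPDH, the 3′ and the middle one were low on sensitive X-ray replicate 3, at 59.3 and 88.5 against control means of 286 ± 39.6 and 281 ± 37.5 (SD, n = 3) in the same window. The 5′ probe set read 63.6 there against 170 on the control array of the same number, and 48.1 against 88.3 and 44.6 against 68.5 within numbers 1 and 2. Within numbers, 9 of 9 differences of the 3 probe sets were lower after X-rays in this window and 6 of 9 in the resistant window, from 1 gene and so not independent. The 3′ probe set averaged 1001 ± 329 in resistant controls, so younger embryos are a candidate explanation. That array lay at −0.0150 of the distance between windows from the control array of its number, which argues against it. On that array, 11 probe sets lay over 1.5 log2 units below all other arrays of its window. This count was within the 0 to 25 of the other 11 arrays. The arrays had been scaled to a common mean, which removes a loss shared by all probe sets. A general loss of signal on that array can therefore not be judged from this count. The cause stays open, and no biological explanation was tested.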
